A study of Folsomia candida with 112 samples.

How the data were processed

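RNA of whole springtails (Folsomia candida) was measured in 112 samples on 56 2-colour Agilent arrays, 8 arrays on each of 7 slides. Each sample is the animals of 1 jar, about 30 animals that were 23 days old, kept for 2 days in 1 of 26 natural soils (S01 to S28 without 2 numbers) or in 1 of 2 control soils, SLCC and SLCZ. The labels state 50% of the water-holding capacity, 20 °C, 75% relative humidity and 500 ng of labelled RNA per sample. They give the soil per jar as 30 g in the protocol and 25 g in the design text. Each soil has 4 jars, 2 labelled with Cy3 and 2 with Cy5, set against 4 different partner soils. One label spelled SLZC was taken as the missing replicate 2 of SLCZ.

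The scanner files hold intensity values made by the authors with Feature Extraction 9.5.1.1, namely the mean signal and median local background of each spot, not normalized, and processed signals that the program corrected for background and dye within each array. The deposited value table of the series holds log2 values, 1 per spot and channel, normalized within each array by the authors, with no normalization between arrays seen in the values. The comparisons start from the mean signal and median background. The array has 15207 spots for 5069 probes, 3 spots each. Of these probes, 1053 carry a database hit that names a gene, 1268 a hit without an informative name and 2748 none. None of the 27231 genes of the reference table could be matched to the probes, so gene names are those of the array's own annotation, which are best hits in other organisms.

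Signals were background-corrected by normexp with an offset of 50, log ratios were normalized within arrays by loess, and the spots of a probe were averaged, in limma 3.58.1 with statmod 1.5.0 under R 4.3.3. The packages jsonlite 2.0.0 and data.table (version 1.17.8) read the files, and Python 3.11.15 with matplotlib 3.10.9 drew the figures. A probe was tested if at least 2 of its 3 spots were well above background in at least 4 of the 112 samples, which left 4334 probes. Of all cells of the probe by array table, 99 had no usable spot. For arrays, precision is limited by the number of arrays. The percent of spots well above background ran from 60.1 to 84.4 over the samples.

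No array joins the soils hybridized with SLCC (the SLCC-linked set, 10 soils, 40 samples, 20 arrays) to those hybridized with SLCZ (the SLCZ-linked set, 18 soils, 72 samples, 36 arrays). Each set was therefore fitted alone with a limma log-ratio model that has a coefficient per soil and a dye effect per probe, which leaves 10 and 18 residual degrees of freedom. The tests were a moderated F over all soils of a set, the mean of the natural soils against the control soil, each natural soil against the control soil, each soil against the mean of the other soils of its set, and the difference between both effects of natural soils against control, taken from 1 fit over all arrays. The sets were compared with limma's separate-channel model (Aquantile normalization, dye and slide as fixed effects, intraspot correlation 0.301). Only slide 3 carries samples of both sets, 8 of each, so these contrasts are tied through that slide. By scan year, slides 3, 4 and 5 fall in period 1 and slides 6 to 9 in period 2. All 40 SLCC-linked samples and 8 SLCZ-linked ones were thus scanned in period 1, the other SLCZ-linked ones in period 2. The error of all these tests is that between jars, not that between soils. Each set has 1 control soil, so p values against it say nothing about other control soils. P values were adjusted by the Benjamini-Hochberg method over the probes of a comparison, and a probe is called at an adjusted p under 0.05.

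Of 24 gene lists, defined by search terms in the array's annotation, 22 had at least 3 tested probes. The UDP-glycosyltransferases (1 probe) and the metal-binding and transport genes (2 probes) were not tested. Lists were tested against control with camera at a preset inter-gene correlation of 0.01 and again with an estimated one. The between-soil SD of each list was ranked among 10000 random lists matched in 20 intensity bins. The search terms for peptidases also took in some peptidase inhibitors, and the terms missed ACV synthetase (beta-lactam list), Gstm2 (glutathione S-transferases) and acetyl-CoA carboxylase (lipid list), which lie outside these lists.

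Named genes follow a rule: annotated probes that name a gene, 1 probe per gene, the 12 with the largest rise and the 12 with the largest fall among the called probes of each natural against control comparison, up to 20 per F test by between-soil SD, 5 per direction for the difference and for each comparison between the sets, up to 4 members of a list per comparison with the smallest adjusted p, and 3 per direction for each of the 4 soils with most calls against the rest. At most 2 probes without a gene name per direction are given by their ID. Groups, tests, lists, this rule and the alternative settings named next were fixed before the data were examined. They were the program's processed signals, the deposited log2 values, median centring in place of loess, no filter and a stricter one (56 of 112 samples, 3928 probes), slide or replicate number as a block, 1 fit over all arrays, the separate-channel model for the comparisons within a set, no Aquantile normalization, no slide effect, and leaving out single samples or arrays. Array weights, leaving out 2 dim arrays, and a fit to slide 3 with 1 coefficient for the natural soils of a set were added after the data were seen. The fits were tested on simulated data with known changes.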

Results

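Transcript levels were measured in whole Folsomia candida, a soil-living springtail, to see how far it differs between animals kept in different soils. The 26 natural soils and the 2 control soils, SLCC and SLCZ, have 4 jars each. The SLCC-linked set holds SLCC with 9 natural soils (S13, S15 to S21 and S28, 36 natural jars). The SLCZ-linked set holds SLCZ with 17 natural soils (S01 to S12 and S23 to S27, 68 natural jars). The labels do not say what the soils are. Spots well above background made up 71.6 to 81.0% of spots in the SLCC-linked samples (median 77.0%) and 60.1 to 84.4% in the SLCZ-linked samples (median 78.2%). In the control jars these shares were 77.8 to 81.0% for SLCC and 76.4 to 82.0% for SLCZ. The median spot intensity ran from 106 to 1678 over the samples, with a median of 452. Values below are log2 differences ± SE from limma and fold differences, over 4334 tested probes.

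Animals from natural soils had less transcript of the hits to preamylase 1, a heavy neurofilament, a granulins precursor and thioredoxin than animals from the control soil SLCC. Preamylase 1 (Fcc02249), a starch-digesting enzyme, was 2.64-fold lower in natural soils (log2 −1.40 ± 0.30, adjusted p = 0.0231; mean log2 intensity 8.90 ± 0.36, SD, n = 36, against 10.12 ± 0.62, n = 4). Apolipophorins (Fcc02219), the lipid carriers of insect haemolymph, fell 1.98-fold (log2 −0.99 ± 0.13, adjusted p = 0.0121; well above background in 4 of 4 SLCC jars and 23 of 36 natural jars) and acetyl-CoA carboxylase (Fcc00050), which makes the first step of fatty acid synthesis, fell 2.04-fold (log2 −1.03 ± 0.27, adjusted p = 0.0414). Thioredoxin (Fcc04514), a redox protein, fell 2.10-fold and a mu-class glutathione S-transferase, Gstm2 (Fcc05335), fell 2.20-fold (log2 −1.07 ± 0.25 and −1.13 ± 0.21). A granulins precursor (Fcc00593), for secreted growth factors, fell 2.34-fold, the hit to a heavy neurofilament (Fcc01841) 2.44-fold, a tick salivary protein (Fcc05793) 2.40-fold, and the zinc metalloprotease ZmpB (Fcc01212) 2.22-fold. The other named falls were 1.94- to 2.00-fold: a DBH-like monooxygenase (Fcc01289, 2.00), the muscle spring protein titin (Fcc05061, 1.96) and a microtubule-associated protein (Fcc00572, 1.94).

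The largest named rises were smaller. A prolyl 4-hydroxylase alpha subunit (Fcc02629), of an enzyme that modifies collagen, was 1.71-fold higher in natural soils (log2 0.77 ± 0.19, adjusted p = 0.0336). A ubiquitin carboxyl-terminal hydrolase (Fcc01799), which removes ubiquitin, was 1.63-fold higher, a putative cyclase (Fcc03343) 1.60-fold, a beta-hexosaminidase (Fcc01243), a lysosomal sugar-cleaving enzyme, 1.56-fold, and RAB2B (Fcc03403), a GTPase of vesicle traffic, 1.56-fold. ReO_6 (Fcc01019) was 1.61-fold higher, but well above background in 1 of 4 SLCC jars and 34 of 36 natural jars. A short-chain dehydrogenase (Fcc00966) rose 1.51-fold (log2 0.60 ± 0.08), a homolog of fused toes (Fcc00662) 1.49-fold, an LDL receptor-like gene (Fcc04325) 1.46-fold, a cytokine-inducible SH2 protein (Fcc05592) 1.44-fold, Spfh1 (Fcc05631) 1.42-fold and annexin IX (Fcc05133), which binds phospholipids with calcium, 1.33-fold. Among probes without a gene name, Fcc01169 rose 3.63-fold and Fcc00429 rose 2.56-fold, while Fcc03304 fell 5.13-fold and Fcc05932 fell 4.48-fold. In all, 330 probes passed (181 up, 149 down, smallest adjusted p = 0.0121), 70 of them with a gene name (27 up, 43 down); 40 differed over 2-fold, 11 up and 29 down. The 4 SLCC jars carry this count: it was 478 without SLCC replicate 1, 30 without replicate 2, and 0 without replicate 3 or replicate 4. It ran from 56 to 900 over the other settings, under all of which each of the 330 probes that was tested kept its sign. The share of called probes that were higher, 54.8%, was 68.9% with the deposited log2 values and 69.3% with median centring, and 43.8% in 1 fit over all arrays, so the balance of rises and falls depends on the setting.

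Among the gene lists, ribosomal proteins lay lower in natural soils than in SLCC: 34 of 36 members had a negative difference, with a median of −0.21. L22e (Fcc05148) fell 1.28-fold and S12 (Fcc02740) fell 1.24-fold, no member rose, 34 did not pass, and 7 fell when adjusted over the list alone. The list passed the camera test (adjusted p = 3.7e-06), and did not with the correlation among its genes estimated from the data (adjusted p = 0.511 with an estimated correlation). No other list passed. The nearest were cytochrome P450, the oxidases of foreign compounds and hormones, and the esterases (adjusted p = 0.0522 for each). Both passed camera with processed signals (adjusted p = 0.0491 for each) and with replicate number as a block (0.0330 for each). The chitin and immune lists passed in both settings too, chaperones with processed signals alone and muscle genes with the replicate block alone. Of 11 P450 members 1 fell, CYP4C1 (Fcc04064, 1.73-fold, well above background in 26 of 36 natural jars), with a list median of −0.26; adjusted over the list alone 6 fell and 1 rose. Of 6 esterases 1 fell, a carboxylesterase (Fcc04282, 1.72-fold), with 2 falls adjusted over the list alone. Both chaperone members that passed were DnaJ proteins that fell (Fcc01714, 1.30-fold, and Fcc03431, 1.25-fold), and 8 of 10 did not pass. In ion transport 2 of 19 members fell, among them the Na/K ATPase alpha subunit (Fcc04059, 1.75-fold). In the nervous system list 3 of 15 fell, among them a muscarinic acetylcholine receptor (Fcc02109, 1.35-fold). Carbohydrate-digesting enzymes went both ways: beta-hexosaminidase and a fucosidase (Fcc00664, 1.24-fold, well above background in 17 of 36 natural jars) rose, amylase fell and 9 did not pass, with a median of 0.15 and a mean of −0.02. No member passed among 7 chitin and moulting genes (median −0.42), 6 immune genes (median −0.39), 15 members of the glutathione S-transferase list (median −0.20), 16 genes of oxidative phosphorylation, 7 ABC transporters, 6 beta-lactam genes, 3 yolk genes or 3 mobile elements. The search terms missed Gstm2 and acetyl-CoA carboxylase, which passed and lie outside the glutathione S-transferase and lipid lists. A single list member passed among the antioxidants (thioredoxin), peptidases (ZmpB), lipid genes (apolipophorins), muscle genes (titin), proteasome and ubiquitin genes (the hydrolase), histones and cell cycle genes (a HPA2-like acetyltransferase, Fcc04605, fell 1.89-fold, well above background in 11 of 36 natural jars) and microbial genes (Fcc03706, log2 −0.65). Of 21 called list members 10 lost their call with the program's processed signals and 12 with median centring, none turning its sign. L22e (adjusted p = 0.0734 and 0.0973), S12 (0.101 and 0.146), CYP4C1, the carboxylesterase, both DnaJ proteins, the muscarinic receptor and Fcc03706 lost theirs in both, titin with processed signals alone, and the Na/K ATPase, the fucosidase and the acetyltransferase with median centring alone. With processed signals the log2 difference of CYP4C1 was −1.59 (limma adjusted p = 0.0541) and that of Fcc03431 −0.68, both larger than above. L22e then lay at −0.33 and S12 at −0.28.

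**Figure D1:**
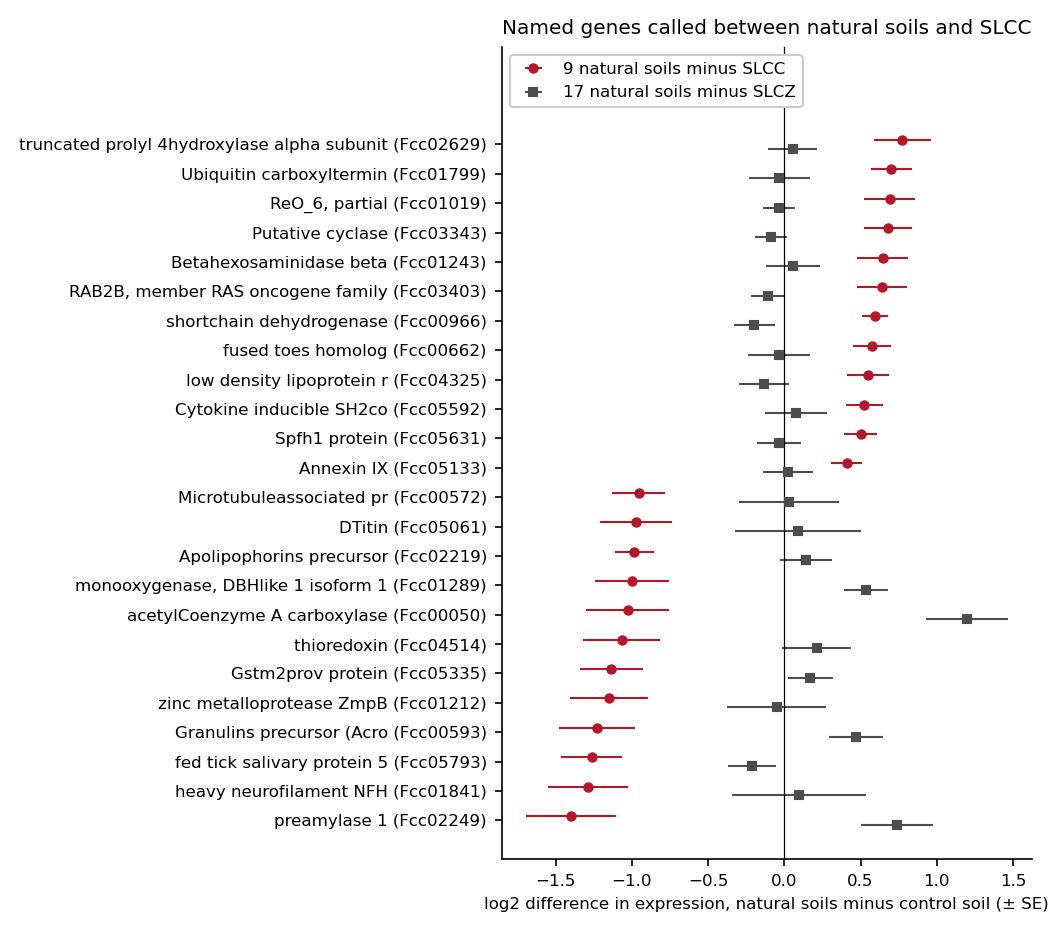
Log2 difference in expression ± SE between natural soils and control soil for the 24 named genes called against SLCC, with circles for the 9 natural soils minus SLCC and squares for the 17 natural soils minus SLCZ. Preamylase 1 (Fcc02249) lies at −1.40 against SLCC and at 0.74 against SLCZ.

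Against the other control soil, SLCZ, no gene passed in natural soils. Limma called 0 probes (smallest adjusted p = 0.0985), with 415 at an unadjusted p under 0.05, 273 of them higher in natural soils. Preamylase 1 (Fcc02249) was 0.74 ± 0.23 higher on the log2 scale (adjusted p = 0.369) and acetyl-CoA carboxylase (Fcc00050) 1.2 ± 0.27 higher (adjusted p = 0.241), both short of the threshold. No member of any list passed. The smallest adjusted p of a list was 0.0831, for ribosomal proteins (median 0.10), esterases (0.16) and carbohydrate-digesting enzymes (0.06), or 0.344 to 0.470 with an estimated correlation. With replicate number as a block, the carbohydrate-digesting enzymes passed camera (adjusted p = 0.0243). The count was 1 without SLCZ replicate 2 and 10 without SLCZ replicate 4, and 1 to 75 in other settings that changed it.

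The effects of natural soils on preamylase 1 and acetyl-CoA carboxylase were not alike against both controls, in a test of the difference itself. The sets share no natural soil, so the difference can lie in the control soils or in the natural soils. Preamylase 1 differed by −2.14 ± 0.38 (adjusted p = 0.00143), acetyl-CoA carboxylase by −2.22 ± 0.39 (adjusted p = 0.00151), a chitinase (Fcc00881) by −2.02 ± 0.50, a polyhydroxybutyrate depolymerase (Fcc00717) by −1.98 ± 0.38 and fasciclin II (Fcc00863), a neural cell adhesion protein, by −2.95 ± 0.80. Fasciclin II was −1.54 against SLCC and 1.41 against SLCZ. On the positive side, the subtilisin-related protease SPC3 (Fcc01701) differed by 1.06 ± 0.28 (0.86 against SLCC, −0.20 against SLCZ), dopamine beta-hydroxylase (Fcc05315), which makes noradrenaline-type transmitters, by 0.99 ± 0.29, a neurotrophic tyrosine kinase receptor (Fcc05220) by 0.87 ± 0.27, a transthyretin-like protein (Fcc02320) by 0.81 ± 0.24 and the short-chain dehydrogenase by 0.79 ± 0.16. Among the lists, 3 of 6 esterases, 3 of 15 glutathione S-transferases, 4 of 36 ribosomal proteins and 3 of 12 carbohydrate-digesting enzymes differed, all with the more negative effect against SLCC, as did 2 of 18 lipid genes; 1 of 26 peptidases differed, in the positive direction. No list was tested as a whole for the difference. Of 29 list members past it, 9 lost their call with processed signals and 13 with median centring, the neurotrophic receptor in both. In all 357 probes differed (128 positive, 229 negative), 180 of them also called against SLCC with the same sign. Of the 330 probes called against SLCC, 98 had the same sign against SLCZ (29.7%), and across all tested probes both effects had a correlation of −0.27, with probes that are not independent. The count was 563 without SLCC replicate 1, 85 without SLCC replicate 4, 84 without SLCZ replicate 1 and 225 without SLCZ replicate 3, and 145 with slide as a block; 35.9% of the called probes were positive, and 52.8% with the deposited log2 values.

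Among the SLCZ-linked soils, ACV synthetase (Fcc00170), the first enzyme of penicillin synthesis, varied most of the named genes past the F test. It had a between-soil SD of 0.94 (adjusted p = 0.0166) and was highest in S12 (log2 2.07 above the mean of the soils), then in S23 (1.28), and lowest in S07 (−1.20), a 9.63-fold range. A putative membrane protein with a Streptomyces hit (Fcc03091) was also highest in S12 (1.26) and lowest in S04 (−0.80, 4.18-fold range, adjusted p = 0.0148). Theromacin (Fcc05207), an antimicrobial peptide of annelids, was highest in S02 (0.51) and lowest in S06 (−0.55, 2.09-fold range, adjusted p = 0.0451). These 3 were the named genes among 15 probes past the F test, and 737 passed at an unadjusted p under 0.05. Of the others, Fcc04512, Fcc03317, Fcc04611, Fcc05964, Fcc05311 and Fcc01723, with no gene name, were also highest in S12 and second highest in S23, with ranges of 4.02- to 12.0-fold. The largest SD was that of Fcc04512 (1.18). The smallest adjusted p (3.9e-04) belonged to Fcc06085 (SD 1.02), highest in S04 (1.21) and lowest in S26 (−1.71). Leaving out 1 of the 36 arrays at a time moved the count to 4 to 9 for 14 arrays and to 24 or 25 for 3; the lowest came without the array of SLCZ replicate 3 and S12 replicate 2, the highest without that of S26 replicate 4 and S11 replicate 3. It was 3 with slide as a block, 9 with no filter, 45 with 1 fit over all arrays, 150 in the separate-channel model, 30 with replicate number as a block and 270 with array weights.

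**Figure D2:**
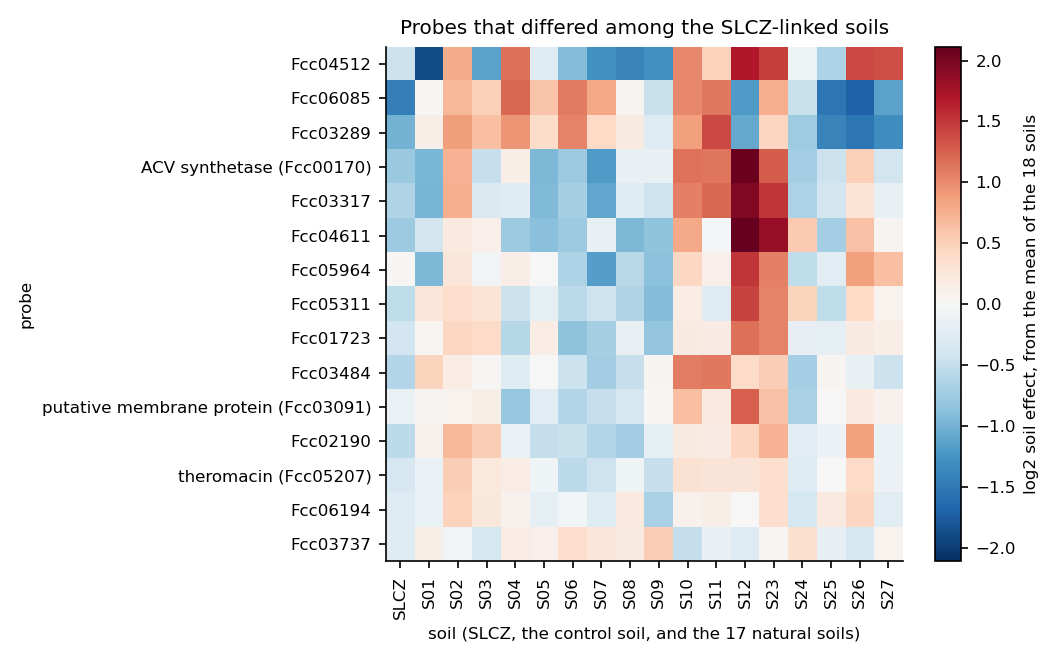
Log2 effect of each of the 18 SLCZ-linked soils (columns), relative to the mean of these soils, for the 15 probes that passed the F test among them (one to a line, red higher and blue lower). ACV synthetase is highest in S12 at 2.07 and lowest in S07 at −1.20.

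Among the SLCC-linked soils no gene passed the F test in limma, with 331 probes at an unadjusted p under 0.05 (smallest adjusted p = 0.467). Isopenicillin N synthetase (Fcc00057), which forms the penicillin ring after ACV synthetase, ran from 1.32 in S20 to −2.04 in S28 there (adjusted p = 0.520). The count was 1 without the array of S17 replicate 2 and S20 replicate 2, 98 with 1 fit over all arrays and 371 in the separate-channel model. No probe passed in both sets. At an unadjusted p under 0.05, 83 did, against 56.3 from chance (one-sided Fisher's exact p = 6.8e-05, with probes that are not independent). Across probes the between-soil SDs of the sets had a Spearman correlation of 0.65, or 0.56 with mean intensity taken out, beside 0.67 for the residual SDs and 0.14 for the F statistics.

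S12 differed from the other SLCZ-linked soils by higher isopenicillin N synthetase and ACV synthetase. Isopenicillin N synthetase (Fcc00057) was 4.65-fold higher there (log2 2.22 ± 0.43, adjusted p = 0.0241), ACV synthetase (Fcc00170) 4.57-fold (2.19 ± 0.37, adjusted p = 0.00802) and the putative membrane protein (Fcc03091) 2.52-fold (1.33 ± 0.20, adjusted p = 0.00479). All 9 probes called in S12 were higher, among the unnamed Fcc04611 (4.71-fold) and Fcc03317 (4.18-fold). A further isopenicillin N synthetase probe (Fcc01821) was 1.66 ± 0.37 higher and did not pass (adjusted p = 0.0667). Probes Fcc05602 and Fcc04050, named for related synthases, differed by 0.10 and 0.00, and the cephalosporin hydroxylase CmcI (Fcc00074) was lowest in S12 (−0.37 from the mean of the soils, F test adjusted p = 0.391). The count in S12 was 0 without the array of S12 replicate 4 and S02 replicate 4, and 0 with slide as a block. In S09, 13 probes passed, none with a gene name: Fcc05974 (2.46-fold) and Fcc03737 (1.47-fold) were among 3 higher, Fcc00272 (3.84-fold) and Fcc00101 (2.30-fold) among 10 lower. Without the arrays of S09 replicate 3 or S09 replicate 4 that count was 0, and with slide as a block 0. In S08 the unnamed Fcc04950 (2.89-fold) and Fcc02252 (2.75-fold) were lower, a count that was 0 without the arrays of S08 replicate 2 or S08 replicate 3. In S04, 1 probe was higher. SLCC differed from the rest of its set by the 330 probes above, and no single natural SLCC-linked soil by any probe (limma, 70 to 250 at an unadjusted p under 0.05).

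Against the control soil, S28 differed from SLCC by 139 probes (46 up, 93 down) and S16 by 27 (8 up, 19 down). They shared 19 (6 up, 13 down), both being set against the same SLCC jars. For S28 against SLCC the count was 431 without SLCC replicate 1, 0 without replicate 2 or replicate 3 and 65 without replicate 4. For S16 against SLCC it was 352 without replicate 1 and 0 without any of the others. The other SLCC-linked soils gave 0 probes each in limma, with 545 to 860 at an unadjusted p under 0.05. The soils' effects against SLCC correlated across probes with a median r of 0.755, against 0.505 in simulations where the SLCC jars alone are shared, and with 0.198 when both soils of a pair were set against different SLCC jars. The like values for SLCZ were 0.499, 0.490 and 0.017. Against SLCZ, 15 probes were higher in S12, 9 differed in S08 (2 up, 7 down), 3 were higher in S06, 2 in S10 and 1 in S09. The median count per soil was 0 against either control and against the rest of either set.

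Peptidases and immune genes varied more between soils than random lists in both sets. The between-soil SD of the 26 peptidases and their inhibitors lay at percentile 100 of random lists matched on intensity in the SLCC-linked soils and at 99.9 in the SLCZ-linked ones. The 12 carbohydrate-digesting enzymes lay at 98.5 in both, the 6 immune genes at 99.7 and 99.9, and the 15 nervous system genes at 99.3 and 99.0. Ribosomal proteins lay at 0.10 and 1.53. The proteasome and ubiquitin genes lay at 0.04 and 5.0. In the SLCZ-linked soils with processed signals the nervous system list lay at 85.8 and ribosomal proteins at 2.74, and carbohydrate-digesting enzymes lay at 97.4 in the SLCC-linked soils. A list was counted as high or low if it lay in the highest or lowest 2.5% of random lists. In the SLCC-linked soils the lipid (99.95), chitin and moulting (99.1), ion transport (99.1) and beta-lactam (98.3) lists were also high, ion transport at 81.3 with processed signals. In the SLCZ-linked soils the beta-lactam list lay at 56.2, but at 99.97 with the stricter filter and 99.0 with processed signals. The residual SD, between jars of the same soil, placed the peptidases at 100 and 97.4, carbohydrate-digesting enzymes at 98.6 and 99.5, immune genes at 99.9 and 99.6, nervous system genes at 99.3 and 97.2 and ribosomal proteins at 0 and 0.07, so these lists varied alike between jars of 1 soil. Percentiles of the F statistic, which sets both against each other, were 61.5 and 69.3 for peptidases, 92.3 and 51.1 for carbohydrate-digesting enzymes, 89.6 and 96.1 for immune genes, 98.6 and 82.6 for nervous system genes and 50.7 and 8.16 for ribosomal proteins. In the SLCC-linked soils, residual SD percentiles were 99.1 (lipid), 99.35 (chitin and moulting), 99.46 (ion transport) and 98.79 (beta-lactam). These lists thus also varied between jars of 1 soil. Their F percentiles were 92.8, 85.4, 72.8 and 90.3, in the same order, none of them in the highest 2.5%. A single list member passed the F test over all probes, the putative membrane protein Fcc03091 of the microbial list.

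**Figure D3:**
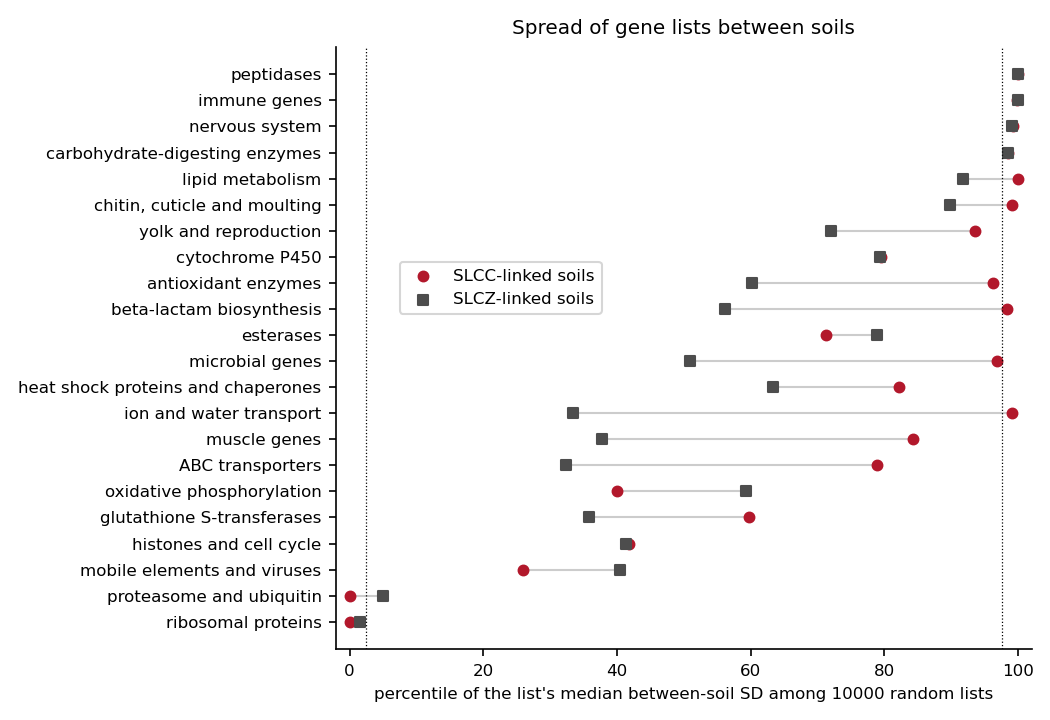
Percentile of the median between-soil SD of each gene list among 10000 random lists matched on intensity, for the SLCC-linked (circles) and the SLCZ-linked (squares) soils, with dotted lines at the bounds beyond which a list was counted as high or low. Peptidases lie at 100 and 99.9 and ribosomal proteins at 0.10 and 1.53.

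Animals from the control soils differed from each other in over 1000 probes, among them many ribosomal proteins; no list was tested as a whole between the sets. In SLCC 23 of 36 ribosomal members were higher than in SLCZ and 1 was lower (median 0.70), with S19e (Fcc00886) 3.80-fold (adjusted p = 3.7e-06), the S30e fusion (Fcc04017) 2.54-fold, P2 (Fcc00668) 1.99-fold and L12 (Fcc02506) 1.93-fold. Vitellogenin I (Fcc05618), a yolk precursor, was 2.93-fold higher (log2 1.55 ± 0.28) and CYP15A1 (Fcc02595), of juvenile hormone synthesis, 3.08-fold. The 3 yolk genes did not rise together: their median was −0.44, and 1 was lower when adjusted over the list alone. Of 26 peptidases and inhibitors 10 were higher and 2 lower, with the protease legumain (Fcc03042, 2.52-fold) and trypsin I (Fcc00536, 2.43-fold) higher and SPC3 (Fcc01701) lower (log2 −1.14). Thioredoxin (2.45-fold), a phospholipid-hydroperoxide glutathione peroxidase (Fcc06123, 2.23-fold) and Cu/Zn superoxide dismutase (Fcc01344, 2.00-fold) were the 3 of 12 antioxidants that were higher. The largest named differences were dumpy (Fcc01510), a giant extracellular matrix protein, 8.12-fold (log2 3.02 ± 0.76, n = 4 and 4 jars), the antimicrobial peptide Alo2 (Fcc05968) 5.01-fold, intestinal mucin (Fcc00226) 4.5-fold, copine (Fcc00253), which binds membranes with calcium, 4.42-fold and a group 2 allergen (Fcc04297) 3.97-fold. Lower in SLCC were a xylan-degrading xylanase (Fcc04469, 3.16-fold, log2 −1.66 ± 0.51), the cephalosporin hydroxylase CmcI (Fcc00074, 3.01-fold), a methyltransferase (Fcc01512, 2.78-fold), an ankyrin (Fcc01237, 2.70-fold) and Su(var)205 (Fcc02794), a heterochromatin protein, 2.64-fold. In all 1563 probes passed (776 up, 787 down). The count was 562 without SLCC replicate 4 and 1004 without SLCZ replicate 1, the control jars on slide 3. Without Aquantile normalization the median of all probes was −0.35 and 63 of 1155 called probes were higher in SLCC; relative to that median, ribosomal proteins were then at 0.91, P450 at 0.55 and peptidases at 0.42. The allergen (adjusted p = 0.0652) and 38 of 66 called list members, the S30e fusion, trypsin I and the antioxidants here among them, lost their call then.

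The natural soils of the sets differed in single ribosomal, proteasome and transport genes, with the error taken between jars, not between soils. In SLCC-linked natural soils 15 of 36 ribosomal proteins were higher than in SLCZ-linked ones and none was lower (median 0.30), led by S19e (Fcc00886, 2.19-fold, adjusted p = 1.6e-05), and 9 of 18 proteasome and ubiquitin genes were higher (median 0.23), among them the proteasome Z subunit (Fcc00064, 1.29-fold). Of 7 ABC transporters 4 were lower (median −0.31), and 5 of 19 ion transport genes were lower and 1 higher. Vitellogenin I (Fcc05618) was 1.67-fold higher and yolk polypeptide 2 (Fcc02167) 1.59-fold lower. Copine (Fcc00253) was 4.78-fold higher (log2 2.26 ± 0.25, adjusted p = 7.3e-10, 36 and 68 jars), dumpy (Fcc01510) 3.84-fold, a thioredoxin-related protein (Fcc05401) 2.88-fold, intestinal mucin (Fcc00226) 2.87-fold and a pancreatic lipase-like enzyme (Fcc02519) 2.64-fold. Lower were cervical cancer proto-oncogene 5 (Fcc03177, 2.32-fold), an ABC substrate-binding protein (Fcc05098, 2.29-fold), fasciclin II (Fcc00863, 2.24-fold), the purine synthesis enzyme Ade5 (Fcc05927, 2.17-fold, log2 −1.12 ± 0.14) and SMC3 (Fcc05201), a cohesin subunit, 2.08-fold. With no slide effect SMC3 (log2 −0.06) and 8 of 55 called list members lost their call, proteasome Z (0.07, adjusted p = 0.112) among them, and 3 turned their sign; with processed signals the ABC substrate-binding protein lost its call (adjusted p = 0.0610). In all 1279 probes passed (621 up, 658 down); 807 were also called between the control soils, 797 in the same direction, both comparisons being tied through slide 3. The count was 2100 in a fit to slide 3, the only slide with both sets (7 natural jars of each), and 2673 with no slide effect, where 1177 of the 1279 kept their sign, 1024 kept their call and the median ratio of the difference to that with slide effects was 0.63. Without Aquantile normalization the median of all probes was −0.45, 28 of 1499 called probes were higher, and the proteasome median turned to −0.14; relative to all probes it was 0.31 and that of ribosomal proteins 0.56. Dumpy (adjusted p = 0.0672), the thioredoxin-related protein, intestinal mucin, fasciclin II and 28 of 55 called list members, S19e, proteasome Z and vitellogenin I among them, lost their call then.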

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

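The fit to slide 3, the test of probes that rise and fall together, and the 3 splits for the highest count of any soil were chosen after the results they test were seen. For the other tests in this part, the outcomes for and against were set beforehand. Those on S12, on single soils and on the unequal counts against the control soils still address patterns already seen.

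The effects of natural soils against control on preamylase 1 and acetyl-CoA carboxylase differed between the sets, which share no soil, in a test of the difference itself. It passed for 357 probes, among them preamylase 1 (Fcc02249, −2.14), acetyl-CoA carboxylase (Fcc00050, −2.22), a chitinase (Fcc00881, −2.02), a polyhydroxybutyrate depolymerase (Fcc00717, −1.98), fasciclin II (Fcc00863, −2.95), SPC3 (Fcc01701, 1.06), dopamine beta-hydroxylase (Fcc05315, 0.99), a neurotrophic tyrosine kinase receptor (Fcc05220, 0.87), a transthyretin-like protein (Fcc02320, 0.81) and a short-chain dehydrogenase (Fcc00966, 0.79), all as log2 differences. A few single samples stood far from the other jars of their group. In S25 replicate 1, 60.1% of spots were well above background, against 77.2 to 80.2% in the other S25 jars, and in S15 replicate 3 it was 78.4%, against 74.5 to 75.1%. These were 2 of 28 groups, where chance gives about 1 in 20. The unnamed probe Fcc00429 had a log2 intensity of 11.91 in SLCC replicate 4, against 12.99 to 13.20 in the other SLCC jars, 1 of 28 named genes and probes looked at.

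Natural soils differed from SLCC by 330 probes, amylase and thioredoxin among them, and from SLCZ by 0. A single deviating SLCC jar is argued against: the 330 top-ranked probes of a fit without a jar kept their direction on that jar's array in 78.8% of cases at the lowest, for jar 1, and in 81.2 to 97.9% for the others, against 58.4 to 74.3% for all probes. A dye bias that differs between slides is argued against as the whole cause by the size of the effects. With a dye effect per slide the median effect was 0.919 times that without. Only 157 probes then passed, 144 of them among the 330. Weaker signal in the SLCZ-linked arrays is argued against by residual SDs only 1.13 times larger and effects against SLCZ −0.17 times those against SLCC. A difference of the control soils, or of the natural soils set against them, stays open. Both differed between the sets in the separate-channel model (1563 and 1279 probes), which cannot tell the soils from a batch that follows the sets. How far each part makes up the unequal counts was not tested. The scan period also differed between most samples of the sets, and its part was not tested. No probe passed between natural soils and SLCC without SLCC replicate 3 or without SLCC replicate 4, so the count of 330 rests on these jars.

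Over 1000 probes differed between the sets of soils, ribosomal proteins among them. A batch between slides or their scans is argued against as the whole cause for the natural soils. The fit to slide 3, which carries 7 natural jars of each set, called 2100 probes between them. This fit is not separate from the comparison over all slides, which is tied through slide 3 as well. The sets lay on different arrays of slide 3, 4 of each, so a difference between those arrays stays open. For the control soils a slide or scan batch stays open, since slide 3 carries 1 jar of each. Exposure, extraction or labelling of the sets at different times cannot be told apart from the soils, since 0 soils were carried by both sets. The soils themselves stay open as a cause, untested for the same reason.

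ACV synthetase and an isopenicillin N synthetase probe, 2 of 5 probes named for these enzymes, were higher in S12 than in other SLCZ-linked soils. The dim array of S12 replicate 1 is argued against as the cause, since without it the median log2 difference of both called probes was 2.35, although the adjusted p of isopenicillin N synthetase (Fcc00057) was then 0.0586 (2.30 ± 0.52, against 2.22 ± 0.43 with all arrays), with fewer residual degrees of freedom. A change of the whole pathway cannot be told apart from a change of single probes: the other 3 probes had a median of 0.10, but Fcc01821 stood at 1.66. A candidate explanation is a group of probes that rise and fall together, whatever the soil. In the SLCC-linked soils the 2 called probes had a median correlation of 0.587 with the 7 other F-test probes highest in S12. Over the residuals of arrays it was 0.483. The value of 0.587 lay above all 1000 random sets (random median −0.01). Those sets were matched on intensity, not on spread. How unusual 0.587 is among probes that vary as much was therefore not tested. A biological difference of S12 stays open and was not tested.

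Regrouping the same samples at random shows how often a random grouping calls as many probes, each count including the real grouping. It treats the jars as exchangeable. Few groupings called as many for natural soils against SLCC (1 of 100, real 330, highest other 129) and the difference between both effects (2 of 100, 357, 550). The same held for the SLCZ-linked F test (1 of 100, 15, 2), the control soils (1 of 35, 1563, 962) and the natural soils of the sets (1 of 100, 1279, 153). Of the other splits of the control jars, 17 called some probes. Between the sets, the real grouping alone follows the sets, so regrouping cannot tell the soils from a batch that follows them. For natural soils against SLCZ (100 of 100; 0, 1) and the SLCC-linked F test (100 of 100; 0, 3) the real count of 0 is reached by any grouping, so regrouping says nothing about chance there. For single soils chosen by their counts, few groupings called as many for S28 against SLCC (2 of 100, 139, 611) and S16 against SLCC (1 of 100, 27, 0). The same held for S12 against SLCZ (1 of 100, 15, 2) and S08 against SLCZ (1 of 100, 9, 1). It also held for S09 (1 of 100, 13, 10), S12 (1 of 100, 9, 4) and S08 (2 of 100, 2, 2) against the rest. With the choice of the soil counted in, chance cannot be excluded. Some soil reached 139 probes against SLCC in 5 of 100 groupings (highest other 775) and 15 against SLCZ in 14 of 100 (highest other 604). Against the rest of the SLCZ-linked soils, some soil reached 13 in 19 of 100 (highest other 529). Single groupings that call several times the real count suggest a structure among the samples, whose cause was not examined.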

How the results depend on the processing

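Array weights, leaving out the 2 dim arrays and the fit to slide 3 with 1 coefficient per set were chosen after seeing the data; with 1 per soil, the fit to slide 3 could not be fitted. Genes and probes named for the size of their change against SLCC or in the difference gave 722 values in other settings. Of these, 553 kept sign and call, 169 kept the sign but not the call and 0 reversed. Some of the 553 could not change. Leaving out an SLCZ jar or the dim arrays does not touch the fit against SLCC, and the difference always comes from 1 fit over all arrays. Genes named by the F test or between the sets are not among them. Of called list members, between the natural soils of the sets 3 of 55 turned their sign with no slide effect, 1 of them past the threshold (Fcc01714, −0.23, adjusted p = 0.0018), and 5 with no Aquantile normalization, where 2 of 66 did between the control soils. Signal limits the arrays: S25 replicate 1 had the lowest share of spots well above background, 60.1%. The cause of the changes below was not tested.

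Natural soils against SLCC (330 probes) gave 210 with the program's processed signals, 205 with median centring, 157 with slide as a block, 56 with replicate number as a block, 603 with 1 fit over all 56 arrays, 900 in the separate-channel model, 514 with array weights, and 0 to 478 without 1 SLCC jar. The difference between the effects (357) gave 234, 235 and 145 with the first 3 of these, 855 in the separate-channel model, and 84 to 563 without 1 control jar. Natural soils against SLCZ (0) gave 1 in 1 fit, 75 in the separate-channel model, 15 with the replicate block, and 0 to 10 without 1 jar. The F test gave 98 (1 fit) and 371 (separate channel) in place of 0 for SLCC-linked soils, 0 to 1 without 1 array; for SLCZ-linked soils it gave 9 (no filter), 3 (slide block), 45 (1 fit), 150 (separate channel), 30 (replicate block) and 270 (array weights) in place of 15, and 4 to 25 without 1 array. Probes past it in both sets (0) were 6 in 1 fit, 19 in the separate-channel model and 0 to 0 without 1 array. The median count per single soil, 0 throughout, became against SLCC 1 (no filter), 119 (1 fit), 382 (separate channel), 1 (replicate block), 43 (array weights) and 0 to 3 without 1 jar; against SLCZ 1 (1 fit), 16 (separate channel), 4 (replicate block) and 0 to 2; against the rest 1.5 (SLCC-linked) and 2 (SLCZ-linked) in the separate-channel model and 0.5 (SLCZ-linked) with the replicate block, 0 to 0 without 1 array. SLCC against SLCZ (1563) stayed at 1155 to 2042 and was 562 to 1667 without 1 jar. Slide 3 alone, with 1 jar of each, does not test it; the 2214 calls there assume that these jars vary like the others. The natural soils of the sets (1279) gave 2673 with no slide effect, 2100 on slide 3 alone, and 912 to 1515 without 1 array. Gene lists past camera (1) were 0 with an estimated correlation, 6 with processed signals and 7 with the replicate block, carbohydrate-digesting enzymes against SLCZ among the 7. Lists in the highest 2.5% of random lists among soils, counted in each set (12), were 11 to 13, but not always the same lists. With processed signals ion transport and carbohydrate-digesting enzymes left and antioxidants entered (SLCC-linked). The nervous system list then left, and ABC transporters, oxidative phosphorylation and the beta-lactam list entered (SLCZ-linked). With the stricter filter P450 entered (SLCC-linked), the nervous system list left and the beta-lactam list entered (SLCZ-linked). Without the dim arrays carbohydrate-digesting enzymes left (SLCZ-linked).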

Other observations

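Some esterases, glutathione S-transferases and other single genes had effects of natural soils against control that differed between the sets, beyond the genes named above. In the test of the difference, 3 of 6 esterases were more negative against SLCC than against SLCZ: a carboxylesterase precursor (Fcc04282, −1.27), the esterase FE4 hit (Fcc01181, −0.99) and juvenile hormone esterase (Fcc02166, −0.46, well above background in 12 of 36 SLCC-linked natural jars), which breaks down juvenile hormone. Of 15 glutathione S-transferases, which conjugate foreign compounds, 3 were more negative (Fcc04073, −1.22; Fcc01282, −0.49; Fcc01979, −0.37; the last 2 well above background in 4 and 5 of 36 SLCC-linked natural jars), and of 11 P450s 2 were (Fcc00266, −1.47; Fcc01651, −0.45). Both maltase-glucoamylase probes that passed (Fcc00529, −1.75, and Fcc00152, −1.26), lysosomal lipase A (Fcc00596, −0.83), the Na/K ATPase alpha subunit (Fcc04059, −1.36) and aquaporin 9 (Fcc05275, −1.15) were also more negative. None of these lists was tested as a whole for the difference. Juvenile hormone esterase and Fcc01282 lost their call with processed signals and with median centring, lipase A and aquaporin 9 with processed signals, and Fcc01979 and Fcc01651 with median centring. The differences with processed signals were larger: −1.59 for juvenile hormone esterase, −1.84 for Fcc01282, −1.12 for lipase A and −1.36 for aquaporin 9.

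A few defence and antibiotic genes came near the threshold among the SLCZ-linked soils. The antimicrobial peptide Alo2 (Fcc05968) ran from 1.03 in S23 to −1.39 in S08 (adjusted p = 0.0503), and isopenicillin N synthetase (Fcc00057) from 2.09 in S12 to −1.07 in S07 (adjusted p = 0.0503). Between the control soils, lectin 2a (Fcc00508) was 2.58-fold higher in SLCC, prophenoloxidase (Fcc01326) 1.37-fold lower, and 3 of 7 chitin and moulting genes were higher, among them a putative chitinase (Fcc03217, 1.89-fold). Without Aquantile normalization lectin 2a (adjusted p = 0.151) and the chitinase (0.467) lost their call, and prophenoloxidase did with no slide effect (0.145) and with processed signals (0.138).

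In the simulated data, changes of 1.5-, 2- and 4-fold were added together to 67, 67 and 66 of 4334 probes, never 1 size alone. Of the 2-fold changes, natural soils against SLCC recovered 89.6%, natural soils against SLCZ 89.6%, the difference 88.1%, and natural soils of the sets 91.0%. Changes of 1.5-fold were recovered in 59.7%, 76.1%, 35.8% and 70.1%. An F test in which 1 soil alone changed 2-fold recovered 67.2% (SLCC-linked) and 61.2% (SLCZ-linked). The simulated noise was independent between probes and between arrays, with no structure among slides or samples. For natural soils, the change was the same in every natural soil of the changed set. The rates may therefore not hold for the real samples. Replicate numbers were not taken as pairs. Jars with the same number had a mean correlation of 0.01 in the SLCC-linked set and 0.13 in the SLCZ-linked set. Jars with other numbers had −0.037 and −0.056. In the SLCZ-linked set it was 0.07 for jars of the same number on different slides and 0.16 for jars on 1 slide with different numbers. Of the samples, 15 of 40 SLCC-linked and 41 of 72 SLCZ-linked ones correlated best with their own number. A structure by replicate number or slide thus stays possible, and a block by either changed the counts above.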
